A study of Homo sapiens with 9 samples.

How the data were processed

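Gene expression was measured in AG1522 cells, a strain of normal human skin fibroblasts, on single-channel cDNA arrays. Per the labels' protocols, confluent cultures received 250 kV X-rays, the 2 Gy exposure took 3.2 min, and 3 µg of total RNA was reverse-transcribed from oligo-dT primers with a radioactive nucleotide. The labels put 3 arrays in a non-irradiated control group, 3 in a group taken 2 h after 2 Gy and 3 in a group taken 24 h after 2 Gy. The time at which control cells were taken is not given in the sources used here, and a lower dose that the labels mention was not analysed here. The design text of the series calls the irradiated replicates technical, and nothing says that any replicates came from separate cultures. P-values therefore measure the spread between these arrays, which may be technical.

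The deposited values are linear spot intensities, 1 per spot and array, for 9600 spots. The scanner software, background correction and normalization are not given in the sources used here. The unit was read from the values, which have a median of about 2 on each of the 9 arrays, no value below 0 and 28.0% of values at exactly 0. The 384 spots at every 25th position were at 0 on all 9 arrays, as were 623 spots in total. What a deposited 0 stands for is not stated, and such a spot is described here as listed at 0. A difference against a group listed at 0 has no measurable fold.

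Spots were named through the platform annotation, with symbols updated by gene identifier in a RefSeq gene table for 8493 spots. A single gene symbol was available for 8496 spots (6284 genes), several for 21 and none for 1083. The array description states 6424 unique genes. No coordinates are given because the sources name no genome build.

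For the tests, values at 0 were set to the smallest positive value of their array, log2 was taken, and the arrays were quantile-normalized. Each spot was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 3 group means over all 9 arrays and 6 residual degrees of freedom. The contrasts were the difference of each time from control and of 24 h from 2 h, with a moderated F test over the 3 groups. P-values were 2-sided and adjusted by Benjamini-Hochberg over 9600 spots, and adjusted p under 0.05 counted as a call. Because a floor far below 1 unit stretches differences from 0, the log2 differences of such spots follow the floor, and values per array are given in their place. A group listed at 0 on all its arrays adds no spread of its own after quantile normalization. The pooled variance, and so the p-value, of such a spot rests on its other arrays. The scale log2(value + 2), with 2 being the array median, is printed where a size is needed, and it understates changes of dim spots.

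Before the data were examined, 26 gene lists were fixed. They cover DNA repair, cell cycle, histones, stress, inflammation, matrix, proteases and their inhibitors, metabolism, protein synthesis and turnover, and markers of keratinocytes, melanocytes, endothelial cells and leukocytes. A total of 25 lists had at least 5 measured genes and were tested with limma's camera, with a preset correlation of 0.01 and adjustment over the lists within each comparison. Camera with an estimated correlation and fry were run beside it. Each gene entered through its brightest spot.

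The genes named per comparison follow a rule fixed at the same time. It takes the 10 largest rises and 10 largest falls among called spots with 1 gene and no overlap between groups, and up to 4 called members of each list. It adds a fixed panel of 18 genes of the DNA damage response and cell cycle whether or not they pass and, where fewer than 5 spots pass in a direction, the 5 of smallest p. Named genes outside the rule are said to be chosen after their values were seen. Of the panel, 12 genes were on the array by name, in 16 spots. The others, and the result of 1 list, are not reported here. XIST and Y-linked genes were not named.

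Alternatives fixed beforehand were the values without further normalization, median and MAD scaling, filters that leave out the dimmest 25% or 50% of the spots, an intensity trend with robust variance, array weights, the replicate number as a block, averaging of a gene's spots, a fit of only the compared groups, and leaving out each array in turn. A planned pseudocount, the 5th percentile of all values, came out as 0 and could not be used. In its place, and after the data had been seen, log2(value + 2), a floor of 2, the omission of spots at 0 on all arrays, centring within blocks of 25 consecutive spot numbers, and log2(value + 2) with that centring were added.

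The fit was tested on simulated data for the comparison at 2 h over 9600 spots, with 100 spots changed 4-fold and 100 changed 16-fold. The main setting called 18.0% and 47.0% of them (18 and 47 spots), with 20 false calls. That is a larger share of the calls than the threshold on adjusted p is meant to allow. On log2(value + 2) it called 25.0% and 55.0%, with 6 false calls. The changed spots were drawn from named spots with a mean log2(value + 2) above the median over spots, and the simulated noise was independent between spots. On the real arrays, deviations from the group mean correlated between adjacent spots at 0.504 to 0.608. Most spots called in the real data were listed at 0 throughout a group, and 0 were called once the dimmest 50% were left out. That filter ranks spots by mean log2 value with 0 set to the floor, so such spots rank low by construction. Whether the simulated rates hold for such spots was not tested. Correlation and overlap between the comparisons that share the control arrays were set beside values simulated for unchanged groups, over 100 simulations for the correlation and 20 for the overlap. Values for unchanged groups with each group's own spread were worked out from the mean variances, after the results were seen. Arrays give no counts, so the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.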

Results

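RNA from AG1522 human skin fibroblasts was measured on 9 cDNA arrays of 9600 spots, to follow gene expression after X-rays, a sparsely ionising (low-LET) radiation. The arrays formed 3 groups of 3: non-irradiated control cells, cells taken 2 h after 2 Gy and cells taken 24 h after 2 Gy. Each array gave 1 intensity per spot, with an array median of about 2 and the brightest spot at 1155 to 4101. Between 2282 and 3249 spots per array were listed at 0, and 3045 spots were above 0 on all 9 arrays. The percentage listed at 0 was 31.4 ± 2.16 (SD, n = 3) in control arrays, 26.7 ± 0.805 (SD, n = 3) at 2 h and 25.9 ± 1.84 (SD, n = 3) at 24 h. Irradiated minus control came to -5.13 points (2-sided exact permutation test, p = 0.0119, the smallest that the 84 splits can give). Across spots, which are not independent, control arrays correlated with each other at 0.691 to 0.737 on log2(value + 2), control with irradiated arrays at 0.714 to 0.832, and irradiated arrays with each other at 0.785 to 0.889. Array weights were 0.590 to 0.763 for control arrays and 0.781 to 2.03 for irradiated ones. The median difference over spots not at 0 on all arrays was 0.14 at 2 h and 0.13 at 24 h on the log2 scale, against 0.03 at both times without normalization and 0.25 and 0.30 with median and MAD scaling. The direction of every change called below for a named gene was the same under these 3 scalings.

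At 2 h after irradiation, TFPI2, a Kunitz-type inhibitor of serine proteases in the extracellular matrix, rose from 0 on all 3 control arrays to 13.4, 6.54 and 7.14 (limma, Benjamini-Hochberg adjusted p = 8.5e-06). By its mean log2 value over the 9 arrays, with 0 set to the floor, the TFPI2 spot was among the lowest 25%. Its values at 0 on all control and 24 h arrays set that rank, while its 2 h values lay above the array median of about 2. On log2(value + 2) its difference was 2.42 ± 0.16 (SE, n = 3 per group; limma adjusted p = 0.0221). CST3, the secreted cysteine protease inhibitor cystatin C, rose from 0 on all control arrays to 2.33, 3.44 and 3.19 (limma adjusted p = 2.51e-05). It differed by 1.34 ± 0.17 on log2(value + 2) (SE; limma adjusted p = 0.128), and by 0.41 once blocks of 25 consecutive spots were centred. Among the falls, CLDN4, a tight junction claudin, went from 14.5, 0.660 and 5.84 to 0 on all 3 arrays at 2 h (limma adjusted p = 0.00304). EPCAM, an epithelial adhesion molecule, fell from 1.02, 0.441 and 5.39 to 0 (limma adjusted p = 0.00152). Its difference was -1.01 on log2(value + 2) (limma adjusted p = 0.635) and that of the other named spots of its block a median of -1.02, and block centring left -0.19.

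In total 32 of 9600 spots were called at 2 h, 17 of them up and 15 down. An unadjusted p under 0.05 was found for 557 spots (limma), little more than the share of 0.05 that chance alone would give, but for 1246 with median and MAD scaling. The other large rises, each from 0 on the 3 control arrays, were those of CPNE1, a calcium-dependent phospholipid-binding protein, ABCB6, an ATP-binding cassette transporter, QARS1, the glutaminyl-tRNA synthetase, HSD17B8, ECI2, an isomerase of fatty acid oxidation, LDAF1, a lipid droplet assembly factor, S100PBP and TMEM234. CPNE1 reached 2.09, 18.1 and 6.51, and QARS1 reached 2.06, 3.52 and 3.88. S100PBP differed by 0.73 on log2(value + 2), the other named spots of its block by a median of 0.96, and block centring turned its direction, to -0.19. The centring took CPNE1 from 2.20 to 1.35, ABCB6 from 1.77 to 0.91, QARS1 from 1.37 to 0.45, TMEM234 from 1.41 to 0.55, HSD17B8 from 1.31 to 0.38 and ECI2 from 1.03 to 0.64, and LDAF1 stayed at 0.85 and 0.86. The other large falls, each to 0 on all 3 arrays at 2 h, were those of GMFB, UBE2Z, a ubiquitin-conjugating enzyme, BBLN, RAB25, a small GTPase of epithelial cells, SRSF7, a splicing factor, IST1, DUSP22, a phosphatase, and THAP4. GMFB had been at 6.01, 1.80 and 3.39 in control cells, and BBLN at 2.75, 2.11 and 3.38. Block centring on log2(value + 2) took GMFB from -1.44 to -0.69, UBE2Z from -1.29 to -0.66, RAB25 from -1.03 to -0.50, SRSF7 from -1.10 to -0.39, IST1 from -1.13 to -0.65, DUSP22 from -1.27 to -0.64 and THAP4 from -0.85 to -0.47, against -1.23 and -1.21 for BBLN and -1.86 and -1.94 for CLDN4. The unnamed spot 8590, close to BBLN in the same block, was called down as well. All 32 called spots were listed at 0 on all 3 arrays of 1 of the 2 groups, 21 of them lay in a block of 25 consecutive spots with another called spot, and only TFPI2 was called on log2(value + 2). Leaving out 1 array gave 37 to 113 calls: 99, 69 and 113 without control replicates 1, 2 and 3, 50 and 67 without 2 h replicates 1 and 3, and 56 and 50 without 24 h replicates 2 and 3.

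Genes of the DNA damage response and cell cycle fixed beforehand did not pass the test at 2 h. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, is on the array in 3 spots. In its brightest spot, intensities were 18.9, 6.92 and 15.1 in control cells and 38.4, 56.5 and 69.4 at 2 h, a 4.01-fold ratio of means, with every 2 h array above every control array. Over all 9600 spots, these 2 groups were apart in either direction in 9.68%, against 10% by chance without ties. The log2 difference was 2.18 ± 0.61 (SE; limma adjusted p = 0.599), and the 2-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. Another CDKN1A spot read 6.35, 43.5 and 8.52 in control cells and 43.3, 21.1 and 23.3 at 2 h, and the remaining one was at 4.93 or less on all control arrays and 4.70 or less at 2 h. GDF15, a secreted stress cytokine, read 3.93, 0 and 1.48 in control cells and 10.9, 5.67 and 5.38 at 2 h in 1 spot (limma adjusted p = 0.887), and 1.14, 0 and 0 against 9.84, 3.30 and 0 in its other spot. Its 2 spots differed by 1.40 and 1.08 on log2(value + 2) (limma adjusted p = 0.635 and 0.843). Block centring left 1.05 and 0.96 (limma adjusted p = 0.394 and 0.719). CCNB1, cyclin B1, read 3.27, 0 and 3.10 against 5.55, 5.42 and 3.85 (limma adjusted p = 0.893). MDM2, GADD45A, BAX, DDB2, PLK2, TP53I3, CCNG1, PCNA and CDK1 each had overlapping values in the 2 groups, and PCNA was listed at 0 on all 6 arrays.

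**Figure D1:**
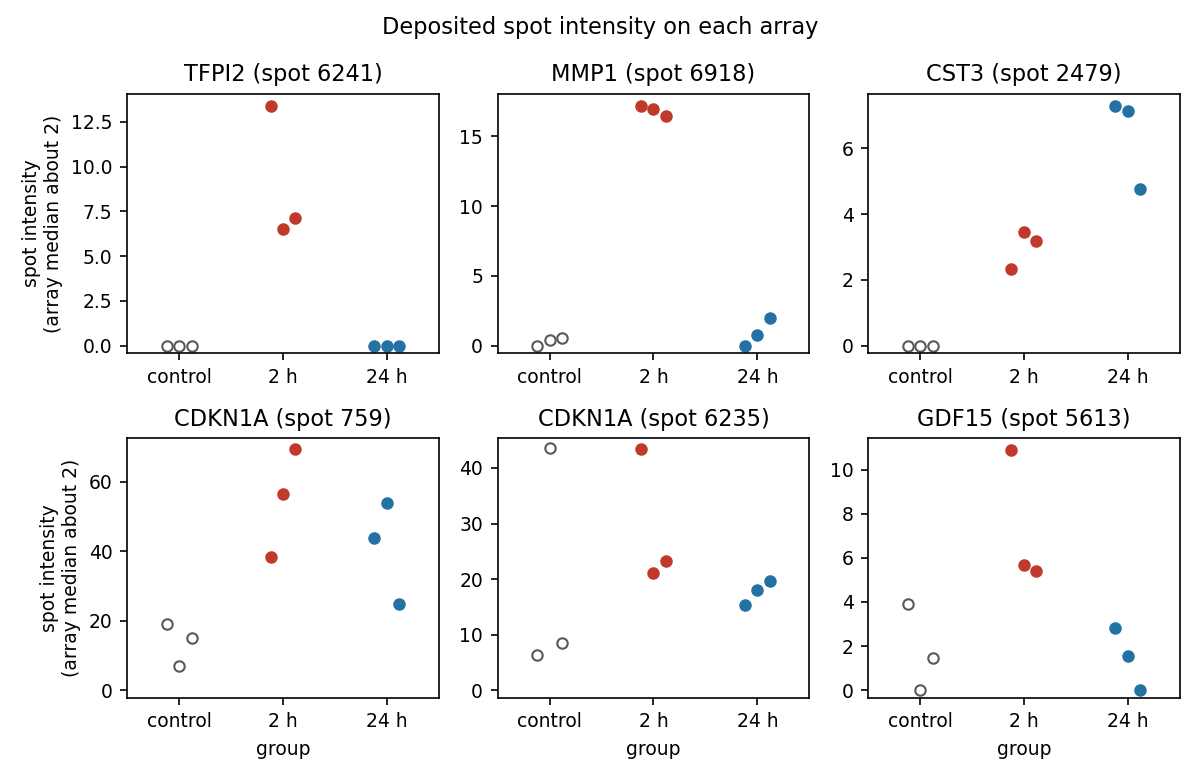
Deposited spot intensity (vertical axis, arbitrary units with an array median of about 2) on each array of the control, 2 h and 24 h groups; each point is 1 array. TFPI2 is at 0 on all control and 24 h arrays and at 6.54 to 13.4 at 2 h, and the brightest CDKN1A spot is above its control values on all irradiated arrays.

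Of the 25 gene lists tested at 2 h, 1 rose, that of proteases and their inhibitors (limma's camera, Benjamini-Hochberg adjusted p = 0.0469; adjusted p = 0.36 with an estimated correlation). Of its 21 measured genes, 17 were higher and 4 lower, with a median log2 difference of 1.41 (0.44 on log2(value + 2)), and 1 member, CST3, rose over all spots tested and also when adjusted over the list alone. Members that did not pass include MMP1, interstitial collagenase, and CTSK, a lysosomal cysteine protease, both chosen after their values were seen. MMP1 was at 0, 0.395 and 0.520 on the control arrays and at 17.2, 16.9 and 16.5 at 2 h (limma adjusted p = 0.882). CTSK was at 0, 0 and 1.53 against 2.21, 4.95 and 6.96 (limma adjusted p = 0.853). The list's call was lost when any 1 array other than 24 h replicate 2 was left out, and with block centring (limma's camera, adjusted p = 0.588). Its median was 0.66 without control replicate 2 and 1.41 to 1.86 without any other array, 0.74 without normalization, 0.81 with MAD scaling, 0.53 with block centring and 0.22 with log2(value + 2) and block centring.

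Among 46 translation factors, EIF2B4, a subunit of the exchange factor eIF2B, rose from 0 to 0.643, 0.384 and 1.77, and EEF1AKMT3, a methyltransferase of elongation factor 1A, fell from 1.38, 0.153 and 0.315 to 0 (limma adjusted p = 0.0261 and 0.0149; 0.49 and -0.48 on log2(value + 2), and 0.40 and -0.24 after block centring). The list's median was 0.10 (limma's camera adjusted p = 0.904). SRSF7, which fell from 6.25, 1.41 and 0.699 in a spot that is not its brightest, differed by 0.55 ± 0.89 (SE) in its other spot (limma adjusted p = 0.951). Of the 50 splicing genes, 25 were higher and 25 lower by their brightest spots, with none called (limma's camera adjusted p = 0.904). Markers of melanocytes (10 genes, median -0.80, limma's camera adjusted p = 0.271) and sterol biosynthesis genes (17 genes, median -1.90, adjusted p = 0.472) had the lowest medians, with no called member, but on log2(value + 2) these medians were -0.50 and -0.28, and with block centring as well -0.37 and -0.09. Keratinocyte markers (16 genes) had a median of 0.27 and leukocyte markers (28 genes) one of -0.12 (limma's camera adjusted p = 0.993 and 0.904), the camera statistic of the keratinocyte list being on the side of lower values. Only 4 endothelial markers were measured, too few for a test. The remaining 17 lists, among them DNA repair (41 genes, median 0.02), mitosis (38 genes, 0.06), histones (20 genes, 0.18) and the proteasome (34 genes, 0.23), had no member called over all spots tested and did not pass (limma's camera adjusted p from 0.472 to 0.993). With block centring the medians of these named lists were -0.11, 0.09, -0.73 and 0.46, so that DNA repair and histones changed sign. Adjusted over the list alone, 2 matrix genes (1 up, 1 down), 3 translation factors (2 up, 1 down), 1 cytoskeletal gene and 1 chaperone (both up) and 1 gene of oxidative phosphorylation (down) were called.

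At 24 h, CST3 was again above the controls, at 7.30, 7.13 and 4.77 against 0 on all 3 arrays (limma adjusted p = 2.58e-05), and TFPI2 was at 0 on all 3 arrays. CST3 differed by 2.13 on log2(value + 2) (limma adjusted p = 0.068), and by 1.03 after block centring. CPNE1 (4.73, 4.86 and 3.40), QARS1 (5.68, 2.87 and 3.61) and LDAF1 (5.09, 1.60 and 5.53) also rose from 0 on all control arrays (limma adjusted p = 0.00174, 0.000121 and 0.00491). Block centring on log2(value + 2) took QARS1 from 1.62 to 0.52, with a median of 1.18 in the other named spots of its block, CPNE1 from 1.70 to 1.26 and LDAF1 from 1.55 to 1.45. CLDN4, GMFB, EPCAM, IST1, DUSP22 and THAP4 fell to 0 on all 3 arrays, as they had at 2 h, and for EPCAM block centring left -0.35 of -1.01 on log2(value + 2). PAPSS1, which makes the sulfate donor of the cell, fell from 2.47, 2.10 and 1.54 to 0, and PSAT1, an enzyme of serine synthesis, from 0.513, 2.03 and 2.12 to 0 (limma adjusted p = 0.00031 and 0.000462). Block centring took GMFB from -1.44 to -0.65, IST1 from -1.13 to -0.59, DUSP22 from -1.27 to -0.74, THAP4 from -0.85 to -0.42, PAPSS1 from -1.0 to -0.52 and PSAT1 from -0.82 to -0.39, against -1.86 and -1.76 for CLDN4.

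In total 29 spots were called at 24 h, 17 up and 12 down, and 432 had an unadjusted p under 0.05 (limma). That is less than the share of 0.05 of all spots that chance alone would give, but median and MAD scaling gave 1179 such spots. HSD17B8, ABCB6, S100PBP, FAM241B, ECI2 and TMEM234 complete the 10 largest rises. HSD17B8, S100PBP and FAM241B differed by 1.53, 1.18 and 1.15 on log2(value + 2), the other named spots of their block by medians of 1.18, 1.21 and 1.21, and block centring left 0.42, 0.08 and 0.05. ABCB6 went from 1.35 to 0.91, TMEM234 from 0.88 to 0.43 and ECI2 from 0.99 to 0.85. HSD17B11 fell from 0.287, 7.03 and 2.42 to 0, and MAGEA3, a cancer-testis antigen, from 2.76, 0.534 and 6.40 to 0.0174, 0.0168 and 0 (limma adjusted p = 0.0321 and 0.0455), with -1.14 and -1.27 on log2(value + 2) and -0.83 and -0.72 after block centring. The brightest CDKN1A spot read 43.8, 53.8 and 24.9 at 24 h, a 2.99-fold ratio of means to control, with a log2 difference of 1.76 ± 0.61 (SE; limma adjusted p = 0.912) and again an exact permutation p of 0.1. GDF15 read 2.83, 1.55 and 0 in 1 spot and 4.47, 6.49 and 0.830 in the other, MDM2 3.82, 6.45 and 6.88, and TP53I3 2.08, 0.493 and 2.01 against 0, 5.36 and 0 in control cells (limma adjusted p of 0.912 or above for these 3 genes). The other panel genes did not pass either. Of the 29 called spots, 96.6% were listed at 0 on all 3 arrays of 1 group, 15 shared a block of 25 consecutive spots with another, and on log2(value + 2) none was called. Leaving out 1 array gave 35 to 105 calls: 105, 66 and 104 without control replicates 1, 2 and 3, and 52 and 57 without 24 h replicates 1 and 2.

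None of the 25 lists passed at 24 h (limma's camera, with 1 list at an unadjusted p under 0.05). The proteasome list came closest, with 24 of its 34 genes higher, 8 lower and a median log2 difference of 0.90 (adjusted p = 0.617). Proteases and inhibitors had 15 genes higher and 6 lower, a median of 0.42 and an adjusted p of 0.798 with camera, while limma's fry, which asks whether the genes move 1 way without comparing them with other genes, gave an adjusted p of 0.00201. On log2(value + 2) the medians were 0.34 for the proteasome and 0.13 for proteases and inhibitors. With block centring they were 0.51 and 0.87, and with both 0.25 and 0.06. Medians of the other cell types' markers were 0.37 for keratinocytes, 0.06 for melanocytes and -0.01 for leukocytes (limma's camera adjusted p = 0.798, 0.917 and 0.956), with the camera statistic of the melanocyte list on the side of lower values. On log2(value + 2) these 3 medians were 0.14, -0.20 and 0.0003, and with block centring as well 0.03, -0.33 and 0.08. The remaining lists had adjusted p from 0.798 to 0.964, and adjusted over the list alone 1 DNA repair gene was called down and 1 cytoskeletal gene and CST3 up.

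**Figure D2:**
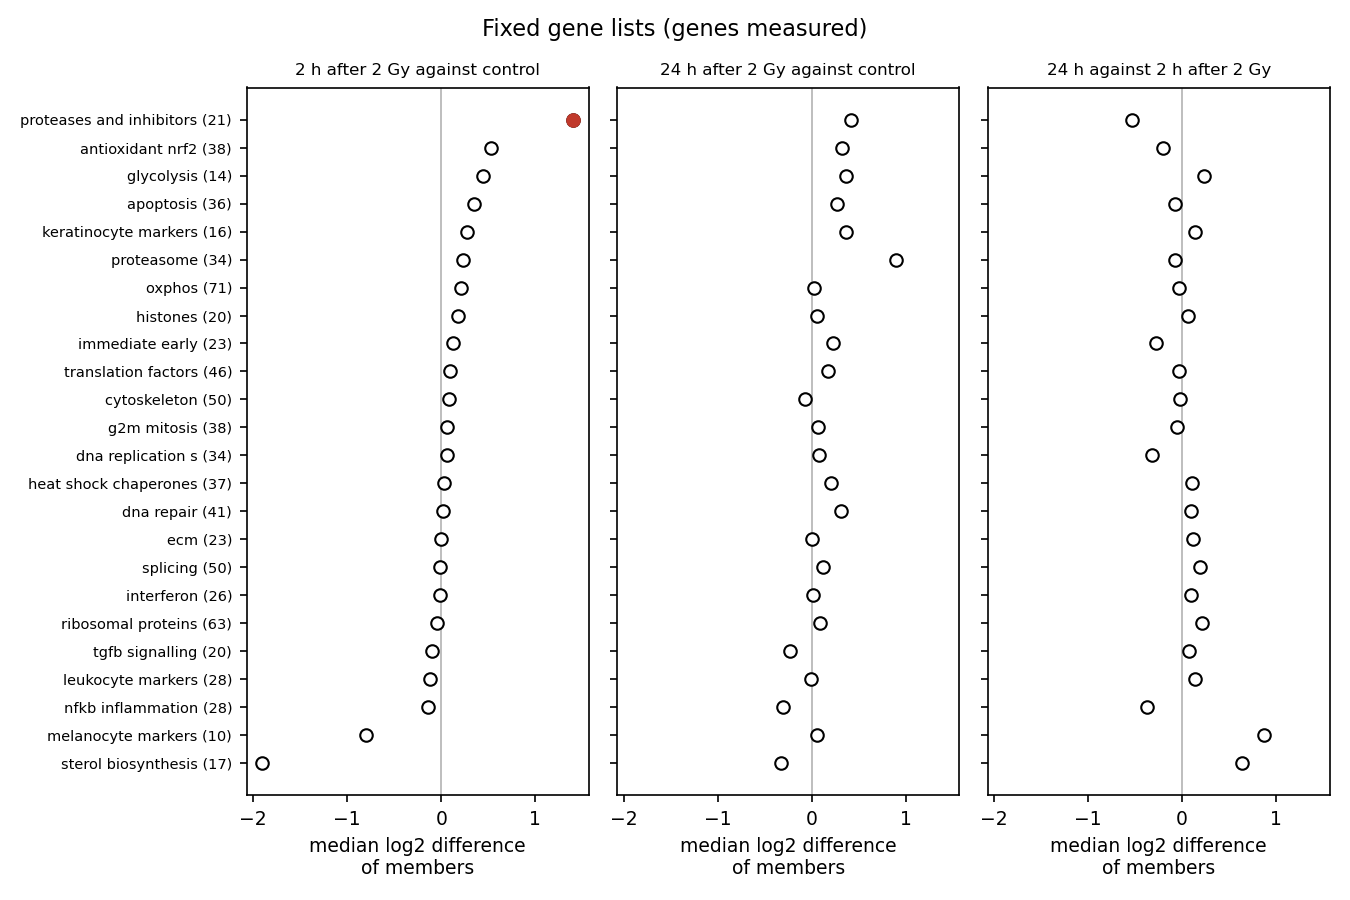
Median log2 difference of the measured members of each of 24 gene lists (rows, number of genes in brackets) in the 3 comparisons; each point is 1 list, and a filled point marks a list that passed (limma's camera). Proteases and inhibitors at 2 h, with a median of 1.41 (0.44 on log2(value + 2)), is the 1 filled point.

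Between 2 h and 24 h, TFPI2 fell from 13.4, 6.54 and 7.14 to 0 on all 3 arrays (limma adjusted p = 8.5e-06; on log2(value + 2) -2.42 ± 0.16 SE, adjusted p = 0.0221). PAPSS1 fell from 0.861, 2.50 and 2.02 to 0 (limma adjusted p = 0.00038). Its difference on log2(value + 2) was -0.89 (limma adjusted p = 0.596), that of the other named spots of its block a median of -0.67, and block centring left -0.26. BBLN, RAB25, SRSF7 and EEF1AKMT3 rose from 0 on all 2 h arrays. BBLN reached 5.45, 3.28 and 10.3 (limma adjusted p = 0.000123), RAB25 4.91, 0.884 and 2.77, SRSF7 4.13, 0.905 and 2.55, and EEF1AKMT3 0.838, 0.704 and 2.31 (limma adjusted p = 0.0121, 0.0279 and 0.0418). Block centring on log2(value + 2) took RAB25 from 1.18 to 0.50, SRSF7 from 1.10 to 0.44 and EEF1AKMT3 from 0.62 to 0.30, and left 1.98 of 2.02 for BBLN and -2.34 of -2.42 for TFPI2. Spot 8590, unnamed and 5 positions after BBLN, had a like course. It was at 2.73, 1.52 and 4.40 in control cells, 0 at 2 h and 6.57, 4.24 and 8.36 at 24 h. Centring on a block median does not remove signal shared by close spots. Within blocks, differences between 24 h and 2 h on log2(value + 2) correlated at 0.528 for spots 5 numbers apart. For spots 4 and 6 apart the correlations were 0.392 and 0.387.

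These named spots and 2 unnamed ones, both higher at 24 h, made up the 8 calls. An unadjusted p under 0.05 was found for 363 spots (limma), again less than a share of 0.05 of all spots. The falls next in order did not pass: HSD17B11 was at 1.34, 4.43 and 0.970 against 0, EIF2B4 at 0.643, 0.384 and 1.77 against 0, and MAGEA3 at 0.790, 1.88 and 3.91 against 0.0174, 0.0168 and 0 (limma adjusted p = 0.0811, 0.0811 and 0.14). None of the panel genes passed, and the brightest CDKN1A spot differed by -0.41 ± 0.61 (SE; limma adjusted p = 1). None of the 25 lists passed with limma's camera, and adjusted over the list alone 1 matrix gene (down) and 2 translation factors (1 up, 1 down) were called. Ribosomal proteins had 46 of 63 genes higher at 24 h and 17 lower, with a median log2 difference of 0.21 (limma's camera adjusted p = 0.509, the other lists being at 0.789 to 0.984), and the list passed on log2(value + 2) (median 0.17, adjusted p = 0.0217; adjusted p = 0.137 with an estimated correlation). All 8 called spots were listed at 0 on all 3 arrays of 1 group, and only TFPI2 was called on log2(value + 2). Leaving out 1 array gave 10 to 35 calls: 17 and 19 without control replicates 1 and 2, 18, 17 and 31 without 2 h replicates 1, 2 and 3, and 24, 35 and 16 without 24 h replicates 1, 2 and 3.

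The differences from control at 2 h and 24 h were compared over all spots. Of the spots called up, 15 were shared between 17 at 2 h and 17 at 24 h, CST3, CPNE1, ABCB6 and QARS1 among them. Of those called down, 9 were shared between 15 and 12, CLDN4, GMFB, IST1 and EPCAM among them. All 15 shared rises were from the same 3 control arrays at 0. Independent lists would share 0.0301 and 0.0188 spots, a value that leaves out the shared controls. Simulated unchanged groups against the same controls shared 0, but they had only 0.1 spots called at 2 h on average, so that value does not show what the shared controls alone would give. Across the 9600 spots, which are not independent, the 2 differences correlated at 0.605, against 0.50 in simulated unchanged groups of equal spread that share the controls, with a covariance of 5.53 against 4.42, a difference of 1.12. The control arrays spread more than the others (mean variance over spots 17.2, against 10.9 at 2 h and 11.5 at 24 h), and with each group's own spread unchanged groups would give 0.607 and a covariance of 5.75. The excess over equal spread may thus come from the shared controls, whose 3 arrays cannot be split into parts of 2 or more. A moderated F test over the 3 groups called 36 spots (limma, adjusted p under 0.05), and 443 had an unadjusted p under 0.05, less than a share of 0.05 of the 9600. With median and MAD scaling 1080 had one.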

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

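The tests of the values at 0, of the splits of the arrays, of the separate CDKN1A spots and of a single value per block as the whole cause, and the settings log2(value + 2) and block centring, were chosen after the results were seen. The 24 h group differed from the 2 h group, under the same contrast with control, in 8 spots by the direct test of that difference (limma, Benjamini-Hochberg adjustment over 9600 spots). TFPI2 was at 13.4, 6.54 and 7.14 at 2 h and at 0 on all arrays at 24 h and in control cells (limma adjusted p = 8.50e-06). PAPSS1 was at 0 on all arrays at 24 h only, against 0.861, 2.50 and 2.02 at 2 h (limma adjusted p = 0.000380). BBLN was at 0 at 2 h only, against 5.45, 3.28 and 10.3 at 24 h (limma adjusted p = 0.000123). An unnamed spot 5 positions after it, number 8590, was at 0 at 2 h and at 6.57, 4.24 and 8.36 at 24 h (limma adjusted p = 0.000123). RAB25 and SRSF7, also at 0 at 2 h only, had limma adjusted p = 0.0121 and 0.0279, and EEF1AKMT3 had 0.0418. The unnamed spot 2586 was at 0 on all control and 2 h arrays and at 0.282, 0.937 and 0.491 at 24 h (limma adjusted p = 0.0279).

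Over the 3 comparisons, 98.6% of the 69 calls (68) had all 3 arrays of a compared group at 0, so the floor that stands in for 0 may set most of these calls, and on log2(value + 2) TFPI2 was the only spot called at 2 h or between 2 h and 24 h. By group, 32, 29 and 8 spots were called, against up to 35, 41 and 17 in the other splits of the same 6 arrays; 2, 5 and 9 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. With the F test over the 3 groups, 36 spots were called by group and up to 52 otherwise, and 31 of 100 drawn splits gave as many, so chance cannot be excluded for that count. On log2(value + 2), 558 spots had an unadjusted p under 0.05 in the limma F test by group, against a median of 460 and up to 783 in the other drawn splits. As many were found in 22 of the 100. Passing the threshold thus does not by itself set a single spot, TFPI2 included, apart from chance. The smallest p-values of the other splits were not kept. A response to radiation is not excluded by these counts.

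Spots of neighbouring number changed together, and deviations of each array from its group mean, which hold no effect of radiation, correlated between adjacent spots at 0.558 on average (0.504 to 0.608 over the 9 arrays), against at most 0.0331 in 1000 random orders of the spots of control replicate 1, so signal or background shared by neighbouring spots may account for part of the differences. Clones of a single gene at adjacent spot numbers are argued against, since only 1 of 8832 adjacent pairs had the same gene symbol, and the 2 h differences correlated at 0.521 without it and at 0.520 over the 7509 pairs of 2 different named genes. Pairs of the same gene farther apart in number were not counted, and the layout of the spots on the array is not known here. A value shared by each block of 25 spots may account for part, since pairs within a block correlated more than pairs across blocks at lags of 2 to 12, by 0.307. Of the variance of the 2 h differences on log2(value + 2), 39.6% lay between blocks, against 4.16% by chance. Of the 32 calls at 2 h, 21 shared a block with another, against a mean of 2.3 and at most 11 in 1000 random draws of spots. At 24 h the number was 15, against 1.96 and 11, and between the times 2, against 0.142 and 4. As the whole cause a single value per block is argued against: it would give the same correlation at all lags within a block, while lags 1 to 11 exceeded lags 12 to 22 by 0.175 (95% range 0.142 to 0.207 over redrawn blocks), with values of 0.521 at lag 1, 0.378 at 3, 0.571 at 5, 0.257 at 13 and 0.0967 at 23, the last under the 0.128 across blocks. CPNE1, ABCB6 and TMEM234 lie in 1 such block and CST3, HSD17B8, FAM241B, S100PBP and QARS1 in the next, and on log2(value + 2) the 2 h difference of CST3 was 1.34 before and 0.41 after block centring, that of TFPI2 2.42 and 2.28; no biological explanation was tested.

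CDKN1A was higher on all 6 irradiated arrays in its brightest spot, without passing the test. Over all spots, irradiated and control arrays were apart in 9.68% at 2 h and 7.48% at 24 h, against 10% by chance without ties. Separation of 3 against 3 arrays alone thus does not mark a response. On log2(value + 2) the difference was 1.98 ± 0.52 (SE) at 2 h and 1.59 ± 0.52 at 24 h. The median of the other named spots of its block came to 0.261 of that difference at 2 h and 0.181 at 24 h, so a shared block value may account for part of it, and neither bound set beforehand (under 0.25 at both times, or over 0.5) was met. Block centring on log2(value + 2) left 1.36 for this spot at 2 h (limma adjusted p = 0.410). The other 2 CDKN1A spots differed by 1.0 ± 0.56 and 0.22 ± 0.77 at 2 h, and 0 of them had all 2 h arrays above all control arrays, so a property of 1 spot and a rise of the gene cannot be told apart with 3 arrays per group and 1 of these spots dim.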

How the results depend on the processing

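The settings log2(value + 2), floor of 2, omission of spots at 0 on all arrays, block centring and their combination were chosen after the data were seen. All others were planned, and the planned pseudocount could not be run because it came out as 0. Counts below are spots called at 2 h, at 24 h, between 24 h and 2 h, and by the F test, against 32, 29, 8 and 36 (limma). Log2(value + 2) gave 1, 0, 1 and 1, a floor of 2 gave 5, 0, 2 and 2, block centring gave 12, 4, 5 and 12, and log2(value + 2) with block centring gave 1, 0, 1 and 0. Leaving out the dimmest 25% of spots gave 20, 18, 6 and 22, and leaving out the dimmest 50% gave 0, 0, 0 and 0. At an unadjusted p under 0.05 (limma) the latter gave 181, 109, 121 and 122, each less than a share of 0.05 of the 4800 spots left. Both filters rank spots by mean log2 value with 0 set to the floor. Spots with a group at 0 thus rank low by construction, and the loss of their calls does not show that they were dim where above 0. A fit of only the 2 groups compared gave 73, 47 and 39. Without further normalization the count between 24 h and 2 h was 13. For values at or near 0 the floor sets the spread by construction, and otherwise the cause was not tested. Counts of calls under array weights, the intensity trend, the averaging of spots, MAD scaling and the omission of spots at 0 stayed within 1.5 times the main ones. Numbers of spots at an unadjusted p under 0.05 (limma) did not: MAD scaling gave 1246, 1179, 314 and 1080, against 557, 432, 363 and 443. Log2(value + 2) with block centring gave 678, 575, 527 and 587.

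Leaving out 1 array gave 37 to 113 calls at 2 h, 35 to 105 at 24 h, 10 to 35 between 24 h and 2 h and 47 to 115 by the F test. The F test gave 115, 79 and 108 without control replicates 1, 2 and 3, 55 and 67 without 2 h replicates 1 and 3, and 56, 73 and 56 without 24 h replicates 1, 2 and 3. The replicate numbers do not pair the arrays: same-numbered arrays of different groups had correlations of deviations from -0.14 to 0.08, 0 of 9 over 0.1, and 0 of the 9 arrays correlated best with its own number. With the replicate number as a block, 25, 18, 4 and 17 spots were called.

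The correlation of the 2 h with the 24 h differences, 0.605, was 0.506 to 0.711 with 1 array left out and 0.552 to 0.648 under the other settings. Unchanged groups sharing the controls would give, from each group's own spread, 0.607 with all arrays, 0.698 with 2 control arrays (0.675 to 0.711 observed) and 0.554 or 0.555 with 2 arrays in an irradiated group (0.506 to 0.577 observed). With equal spread they would give 0.5, 0.6 and 0.447, so the range cannot be read without these values. Of 25 lists, 1 passed at 2 h, and 0 passed without normalization, with either filter on dim spots, with the replicate block, with a floor of 2, without spots at 0 on all arrays, with block centring and with an estimated correlation. MAD scaling gave 3 and log2(value + 2) with block centring 2, and leaving out 1 array gave 0 to 1. At 24 h no list passed, and 1 did with MAD scaling and 1 with fry. Between 24 h and 2 h no list passed, and 1 did with log2(value + 2), 1 with a floor of 2 and 1 with log2(value + 2) and block centring.

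Of 48 calls of named spots, 46 no longer passed on log2(value + 2) and 32 no longer passed after block centring, with the direction kept. Both filters, on the dimmest 25% and 50% of spots, left out the TFPI2 spot, so it was not tested there. In every setting that kept its spot TFPI2 passed at 2 h (limma adjusted p from 5.64e-06 to 0.04996). It was at 0 on all control and 24 h arrays, which after quantile normalization add no spread of their own to the pooled variance. Its SE then rests on the arrays at 2 h, and passing in settings that share this is not independent support. The fall of TFPI2 to 24 h missed the threshold with a floor of 2, at -2.11 ± 0.20 (SE, limma adjusted p = 0.0723). S100PBP at 2 h reversed, to -0.19, with log2(value + 2) and block centring, and the cause was not tested. The array median of about 2 units limits what dim spots show: most called spots lie within a few units of it.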

Other observations

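The genes in the first paragraph, the settings log2(value + 2) and block centring, and all tests in this part were chosen after the values were seen. On log2(value + 2), the spots next to TFPI2 in order of p at 2 h were MMP1, interstitial collagenase, and NME4, a mitochondrial nucleoside diphosphate kinase. MMP1 was higher at 2 h by 2.95 ± 0.26 (SE, n = 3 per group; limma, Benjamini-Hochberg adjusted p = 0.0503), and differed by -2.80 at 24 h from 2 h (limma adjusted p = 0.0808), at 0, 0.785 and 1.95 at 24 h. NME4 differed by -1.62 ± 0.15 at 2 h and -1.58 at 24 h, from 4.97, 3.54 and 5.59 in control cells to 0.359, 0 and 0 at 2 h (limma adjusted p = 0.0503 and 0.087), its other spot by -0.10 and -0.43, and block centring left -1.16 and -1.20. MRPL51, a mitochondrial ribosomal protein, was at 25.4, 21.0 and 26.0 at 2 h against 10.9, 13.5 and 9.30 in control cells and 9.31 to 12.8 at 24 h, and its difference of 1.10 at 2 h was 0.38 after block centring. RBM10, an RNA-binding splicing regulator, was at 9.98 ± 0.982 (SD, n = 3) in control cells, 3.08 ± 0.451 (SD, n = 3) at 2 h and 3.53 ± 0.643 (SD, n = 3) at 24 h (limma adjusted p on log2(value + 2) = 0.128 and 0.283), and block centring took its difference at 2 h from -1.13 to -0.78. CRABP2, a retinoic acid binding protein, was at 76.2 ± 8.91 (SD, n = 3), 48.6 ± 7.99 (SD, n = 3) and 85.3 ± 3.05 (SD, n = 3) in the same order, and TM4SF1 at 7.46, 8.57 and 7.85 at 2 h against 1.13, 1.42 and 1.23 at 24 h.

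TFPI2 and MMP1, a protease inhibitor and a protease of the matrix, had the same course of high values at 2 h and values near or at 0 in control cells and at 24 h. Block centring left 2.28 for TFPI2 and 2.91 for MMP1 on log2(value + 2), of which only TFPI2 passed (limma adjusted p = 0.0498 and 0.0503). Whether the 2 genes share a response was not tested. The list of proteases and inhibitors that holds MMP1 passed at 2 h on log2(value + 2) too (limma's camera adjusted p = 0.0136; adjusted p = 0.227 with an estimated correlation).

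On log2(value + 2) with block centring, proteasome genes were higher at 2 h (34 genes, median 0.19) and melanocyte markers lower (10 genes, median -0.37), both with a limma camera adjusted p of 0.0245 and 0.254 with an estimated correlation. At 24 h these lists had medians of 0.25 and -0.33 (limma's camera adjusted p = 0.05004 and 0.479). Ribosomal proteins were higher at 24 h than at 2 h in this setting (63 genes, median 0.15, limma's camera adjusted p = 0.0308; adjusted p = 0.462 with an estimated correlation).

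The 2 spots of MAD2L1, a spindle checkpoint gene, gave different values. The first was at 16.7, 15.1 and 6.06 in control cells and at 0 on all arrays at 2 h, and the other was at 5.80, 7.68 and 8.96 in control cells and at 9.04 or more on all arrays at 2 h (limma adjusted p on log2(value + 2) = 0.128 and 0.547). SMOC1, 5 positions after the first of these, was at 18.7, 20.4 and 7.14 in control cells and at 0, 0.535 and 0 at 2 h. It differed by -2.83 on log2(value + 2) (limma adjusted p = 0.128) and by -1.81 after block centring. The difference of the first MAD2L1 spot was -2.67 before and -1.65 after block centring.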
